A study of Mus musculus with 6 samples.

How the data were processed

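Total RNA from the uterine horns of C57BL6J mice was measured on a 1-colour Affymetrix whole-genome mouse array, per the labels. Each of the 6 arrays held RNA pooled from 2 uteri, and the cervix was left out. The control group (3 arrays) carried the SF1 transgene SF1-LsL/+ without Cre, and the SF1 group (3 arrays) carried the same transgene with a Cre allele at the Pgr locus, which by design switches the transgene on in Pgr-expressing cells. SF1 is the nuclear receptor encoded by Nr5a1. Tissue was taken 2 weeks after a surgery whose kind, and so the hormonal state of the mice, is not given in the sources used here.

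The deposited values are probe set intensities on a linear scale, between 1 and 25324.74. The software that the authors used for background correction, normalization and summarization is not given in the sources used here. Array medians lay between 149.9 and 162.2 intensity units and the arrays did not share 1 distribution, so no quantile normalization of the final values was visible. Compressed or subtracted background in the unstated summarization would change fold changes of dim probe sets most.

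Of 45101 probe sets, 64 Affymetrix control probe sets were set aside and 45037 were tested. Gene names came from a platform annotation table. It gave 34945 tested probe sets 1 gene symbol, 932 several and 9160 none. Through the gene ID, 34754 symbols matched the GRCm38.p6 gene table as current, 0 were updated, and 204 IDs were absent from that table. A gene (18193 in all) was represented by its probe set with the highest mean over the 6 arrays among those with 1 symbol. Probe sets with several symbols or none were tested but not named.

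Intensities were transformed as log2(value + 16) and fitted with limma 3.58.1 (lmFit and eBayes, default settings) in R 4.3.3. Fold changes are on that scale and understate the change of dim genes. Benjamini-Hochberg adjustment covered all tested probe sets, and a gene was called at an adjusted p under 0.05. All adjusted p-values of single genes are from this limma fit. Tables were read with pandas 2.3.3 and drawn with matplotlib 3.10.9 in Python 3.11.15.

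Before the data were examined, 39 gene lists of uterine, steroidogenic and cell type marker genes were fixed from textbook knowledge. Of their 824 entries, 740 were measured under that symbol or a synonym. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists. Beside it stand camera with a correlation estimated per list, and fry, which asks whether members move one way (directional) or in either direction (mixed) without comparing them with other genes.

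The rule for named genes was also fixed before the data were examined. It took Nr5a1 and Pgr, the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap, up to 2 called members with the largest rise and up to 2 with the largest fall from each described list, and the main steroidogenic genes. Clone and predicted gene names were passed over (1 among the highest, 0 among the lowest). Cyp19a1 had no probe set with its symbol alone in the table used here.

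The alternatives fixed in advance were quantile normalization, median centring, a filter to the brighter probe sets, the replicate number as a block, eBayes with trend and robust, array weights, each array left out in turn, the mean of a gene's probe sets, pseudocounts of 1 and 64, a fold of at least 1.5 in addition, an adjusted p under 0.01, and the other list tests. Alternatives kept the probe set that represented a gene in the 6 arrays. That choice was made after a first run of the left-out arrays, which chose it again each time, had turned the sign of Cyp11a1. The version chosen again stands beside it as an added alternative.

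The fit was tested on simulated arrays with the observed spread, in which 200 of 45037 probe sets were changed. It called 12% of those changed 1.3-fold, 70% at 1.5-fold, 96% at 2-fold and 100% at 4-fold. It also called 7 unchanged probe sets, which is 0.0156% of the unchanged ones and not the share of false calls among calls. In the real arrays 6291 probe sets were called. The same adjusted p then stands for another unadjusted p, so these shares need not hold there. With 18193 simulated genes, camera called 2 of 2 shifted lists and 0 of 37 unshifted lists at an adjusted p under 0.05. Regroupings of the real arrays that mixed control and SF1 gave between 6 and 11 called lists. Each regrouping kept part of the difference between SF1 and control, so these calls need not be false. Neither the simulation nor the regroupings set the rate of false list calls in the real arrays. The number of arrays limits the precision: the median SD of log2 values between arrays was 0.108 in control and 0.1 in SF1. The labels describe separate pools, but not whether pools were processed together.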

Results

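The arrays compared uteri labelled as carrying Cre and a transgene for SF1, a transcription factor of steroidogenic tissues (SF1 below), with uteri labelled as carrying the same transgene without Cre (control). Each group had 3 arrays, and each array held a pool of 2 uteri. Median intensities were 159, 162.2 and 161.9 in control replicates 1 to 3 and 149.9, 159.6 and 155.1 in SF1 replicates 1 to 3. Mean correlations of an array with its own group lay between 0.9888 and 0.9925, and with the other group between 0.9672 and 0.9761. The ratio of 3' to 5' signal of the beta-actin control probe sets, a sign of RNA quality, was 2.508 ± 0.107 in control and 2.194 ± 0.123 in SF1 (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 can give). The same ratio for Gapdh was 1.624 ± 0.0876 and 1.541 ± 0.104 (exact permutation p = 0.3).

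Nr5a1, the gene of the transgene, was measured first. Its brighter probe set gave 151.69 ± 17.4 in control and 151.3 ± 0.131 in SF1 (SD, n = 3), a log2 difference of 0.00 with a 95% interval from -0.21 to 0.21 (limma adjusted p = 0.992). The other probe set gave 0.08 (adjusted p = 0.535). A probe set outside the cDNA of a transgene does not see it, and the position of these probe sets relative to the transgene is not known here, so they check neither the labels nor the expression of SF1. Pgr, the progesterone receptor and the locus of the Cre allele, fell from 4797 ± 89 to 1893 ± 158 intensity units, a log2 change of -1.34 ± 0.09 (SE; limma adjusted p = 3.23e-05). Its other probe sets also fell, with log2 changes of -0.79 and -0.90. Only the SF1 group carried the Cre allele, so Pgr dose, Cre and SF1 differed together.

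The highest rise in SF1 was that of Akr1cl, an aldo-keto reductase gene, from 44.3 ± 3.51 to 9137 ± 650 intensity units (log2 change 7.25 ± 0.09, SE; limma adjusted p = 4.62e-09). Nr0b1 (Dax1), a nuclear receptor gene and known target of SF1, rose from 23.6 ± 2.56 to 1289 ± 104 (5.04 ± 0.09; adjusted p = 7.52e-08). The other genes with the largest rises were Ccdc153 (5.32), Dynlrb2 (4.63), Tmem212 (4.46) and Hoatz (4.40), the chemokine Cxcl5 (5.01), the gut hormone gene Pyy (4.64), Chga (4.49), which encodes a protein of hormone granules, and Ltf (4.41), the estrogen-responsive lactotransferrin gene. Cxcl5 varied between the SF1 arrays, at 1246 ± 1252 intensity units, and read highest in SF1 replicate 2. So did Lcn2, Clu, Timp1, Slc26a4, Fos and Junb, described below or called higher. Lcn2 read 11672 there, against 5307 and 3351 in SF1 replicates 1 and 3, and Clu 13822 against 8550 and 4759. All of these genes still read higher in every SF1 array than in any control array. Other risen genes, among them Akr1cl and Ccdc153, read lowest in SF1 replicate 2. The largest falls were those of Aspg (-2.69), the phospholipase gene Pla2g10 (-2.51), Cd83 (-2.45), the noncoding Rmst (-2.37), the gland-expressed chemokine gene Cxcl15 (-2.36), Fads2b (-2.36), Coch (-2.32), C1ql2 (-2.10), Lgi1 (-2.10) and the sulfotransferase gene Sult1d1 (-2.08).

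**Figure D1:**
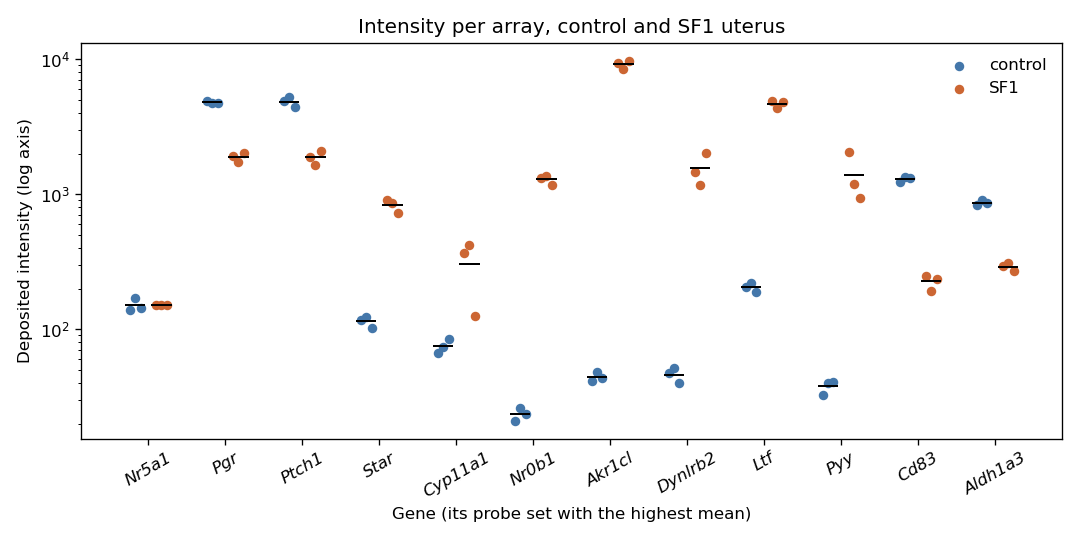
Deposited intensity on a log axis for 12 genes, with 1 point per array (3 control, 3 SF1) and a black line at each group's mean. Nr5a1 lies near 151 in both groups, Pgr is lower in all SF1 arrays, and Akr1cl rises from a mean of 44.3 to 9137.

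Of 18193 genes, 2998 changed at an adjusted p under 0.05, 1523 of them higher and 1475 lower in SF1 (limma). With a fold of at least 2, 374 were higher and 164 lower. The share of calls that were higher was 50.8% in the deposited values, 58% after quantile normalization and 62.8% after median centring, but 46.4% with the filter to brighter probe sets and 46.5% with the mean of a gene's probe sets. Over all probe sets, 2650 were higher and 3641 lower. The groups did not overlap for 7256 genes, where chance gives 10%, and for 2997 of the called genes. Of 1610 called genes with more than 1 probe set, 790 had another probe set called the same way and 8 had one called the opposite way. For some genes named below, no other probe set was called. They include Fkbp5, Wnt7a, Msmo1, Lgr4, Lgr5, Clca1, Cebpb, Foxl2, Cdh5, Oxtr, Cxcl9, Slc26a7, Ctse, Cys1, Cfp and Vegfa. Without SF1 replicate 1 the count was 1933.

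Of the 39 lists, 21 shifted, 14 higher and 7 lower (camera at a preset correlation of 0.01). With an estimated correlation, camera called 0 lists at an adjusted p under 0.05 and 4 at an unadjusted p under 0.05. Mixed fry, which does not test a shift, called 33. Directional fry called 21, but of the lists that camera shifted it did not call macrophages and monocytes (0.057), complement (0.057), skeletal muscle (0.057), uterine epithelium (0.111) or smooth muscle (0.151). It did call 5 lists that camera did not, all lower except mucins and secreted epithelial proteins (0.00751): uterine glands (0.000526), decidual markers (0.0355), the prostaglandin pathway (0.0355) and ovary (0.0417). Camera on ranks ended the calls of SF1 targets (adjusted p = 0.0929), the estrogen response (0.0662), endometrial stroma (0.0604), the retinoid pathway (0.0753) and complement (0.092), and quantile normalization those of uterine epithelium (0.0581), smooth muscle (0.12), complement (0.105) and skeletal muscle (0.0629).

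Genes of steroid hormone synthesis changed in part. Star, which carries cholesterol into mitochondria, rose from 114 ± 11.2 to 832 ± 99.6 intensity units (log2 change 2.70, adjusted p = 4.84e-06), as did both of its other probe sets. Cyp11a1, the side-chain cleavage enzyme, rose by 1.66 (adjusted p = 0.0182) on 1 of its 3 probe sets, and the other 2 were not called. It read 124.8 in SF1 replicate 3, and its call was lost without control replicate 1, SF1 replicate 1 or SF1 replicate 2 (highest adjusted p = 0.073). Hsd3b1 (-0.25, adjusted p = 0.136) and Cyp17a1 (-0.01, adjusted p = 0.982) were not called. Of 24 measured members, 5 rose, 0 fell and 19 were not called (6 rose and 0 fell adjusted over the list alone). Only 3 rose without control replicate 1, SF1 replicate 1 or SF1 replicate 2, and 1 fell without SF1 replicate 2. The list did not shift (camera adjusted p = 0.0858), although it did without SF1 replicate 3 (0.0115). SF1 targets outside steroid synthesis shifted higher (camera adjusted p = 0.0141, and adjusted p = 0.418 with an estimated correlation). Of 19, 6 rose and 1 fell, with Nr0b1 and Vnn1 (2.63), a pantetheinase gene, at the top, and Nr5a2 (-0.95), the close relative of Nr5a1, lower. Adjusted over the list alone, 6 rose and 2 fell, and 2 also fell without SF1 replicate 2. Cholesterol synthesis and uptake shifted higher, with 9 of 20 members risen and 0 fallen (11 and 1 adjusted over the list alone, camera adjusted p = 3.28e-05, and adjusted p = 0.288 with an estimated correlation). Msmo1 (1.44) and Sqle (1.34), enzymes of sterol synthesis, rose most.

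Genes of motile cilia rose together. Of 16 measured members of the list for ciliated cells and oviduct, 12 rose, 1 fell and 3 were not called (12 and 1 adjusted over the list alone). The list shifted higher (camera adjusted p = 4.08e-11, and adjusted p = 0.288 with an estimated correlation), with a median log2 change of 1.75. Dynlrb2, a dynein light chain gene, rose from 46.2 ± 6 to 1555 ± 431 intensity units. Rsph4a, a radial spoke gene, rose from 30.2 ± 2.67 to 527 ± 133 (3.53). Ovgp1, the oviductal glycoprotein gene, was the member that fell (-0.73, adjusted p = 0.00888). Within the SF1 group, Dynlrb2, Rsph4a and Ovgp1 each read highest in replicate 3 and lowest in replicate 2.

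The progesterone response list shifted lower. Of 22 measured members, 2 rose and 13 fell (4 and 15 adjusted over the list alone, camera adjusted p = 0.000461, and adjusted p = 0.288 with an estimated correlation). Besides Pgr, the largest fall was that of Ptch1, the Hedgehog receptor gene (-1.36), while Fkbp5 (1.10) and Wnt4 (0.84) rose. Pgr is itself a member of this list. The estrogen response list shifted higher, with 10 of 23 risen and 4 fallen (11 and 6 adjusted over the list alone, camera adjusted p = 0.00452, and adjusted p = 0.288 with an estimated correlation). Ltf rose from 204 ± 15.2 to 4683 ± 294 intensity units and Sprr2f by 3.89, while Pgr and Clca1 (-1.28) fell. Decidual markers did not shift by camera (3 of 17 rose, 4 fell, 3 and 6 adjusted over the list alone, camera adjusted p = 0.221), with Wnt4 and Cebpb (0.70) higher and Bmp2 (-1.16) and Hand2 (-0.88) lower.

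The uterine epithelium list shifted higher, with 7 of 26 risen and 3 fallen (9 and 4 adjusted over the list alone, camera adjusted p = 0.0218, and adjusted p = 0.568 with an estimated correlation). Krt7 (1.80) and Cdh1 (0.71) rose, and Wnt7a (-1.50) and Cdh16 (-1.03) fell. The list's call was lost without control replicate 3 (0.0673) or SF1 replicate 1 (0.0528), and 4 members rose without control replicate 1, control replicate 3 or SF1 replicate 2 and 3 without SF1 replicate 1. Endometrial stroma shifted lower, with 1 of 22 risen and 10 fallen (1 and 11 adjusted over the list alone, camera adjusted p = 0.0141, and adjusted p = 0.288 with an estimated correlation). Twist2 (-1.54) and Wnt5a (-1.13) fell most, and Pcolce (2.49) rose. Smooth muscle shifted higher with 3 of 24 risen and 2 fallen (5 and 2 adjusted over the list alone, camera adjusted p = 0.0209, and adjusted p = 0.568 with an estimated correlation). Oxtr, the oxytocin receptor gene, rose by 0.60, and Pgm5 fell (-1.23). Casq2 (0.45) and Synpo2 (-0.44) were called with all 6 arrays, but each lost its call in 4 of the fits that left out 1 array (highest adjusted p = 0.12 and 0.0838). The smooth muscle call was lost without control replicate 1 (0.0804) or SF1 replicate 3 (0.0797), and 1 member fell without control replicate 1 or 2 or SF1 replicate 1 or 2.

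Wnt signalling genes shifted lower, with 4 of 33 risen and 13 fallen (4 and 14 adjusted over the list alone, camera adjusted p = 0.00463, and adjusted p = 0.418 with an estimated correlation). Wif1 (-1.70) and Wnt7a fell most, and Sfrp1, a secreted Wnt antagonist gene (2.46-fold), and Lgr4 (1.23) rose. The retinoid pathway shifted lower, with 0 of 21 risen and 6 fallen, also adjusted over the list alone (camera adjusted p = 0.0441, and adjusted p = 0.288 with an estimated correlation). Aldh1a3 (-1.53) and Aldh1a2 (-0.90), which make retinoic acid, fell most, and the list's call was lost without control replicate 3 (0.114) or SF1 replicate 1 (0.0558). Of the hypoxia and glycolysis list, 7 of 20 rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 0.0165, and adjusted p = 0.418 with an estimated correlation). Egln3 rose by 1.18, a call lost in 2 of the fits that left out 1 array (control replicate 1 or 3, highest adjusted p = 0.0713). Ankrd37 rose by 0.90, and Vegfa (-0.82) and Adm (-0.74), both angiogenic factors, fell. Without control replicate 1, 3 members of that list rose.

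The endothelium list shifted lower. Of 17 genes, 1 rose and 14 fell, also adjusted over the list alone (camera adjusted p = 3.7e-06, and adjusted p = 0.288 with an estimated correlation). Cdh5 (-0.83) and Ptprb (-0.77) fell most. Plvap rose by 0.61, a call lost without control replicate 1 or 3 or SF1 replicate 1 (highest adjusted p = 0.073). Macrophage and monocyte genes shifted higher, with 10 of 22 risen and 0 fallen (16 and 0 adjusted over the list alone, camera adjusted p = 1.83e-06, and adjusted p = 0.418 with an estimated correlation). Aif1 rose by 1.45 and C1qa, a complement gene of macrophages, by 1.02. The count of risen macrophage genes was 6 without control replicate 2, 3 without SF1 replicate 1 and 5 without SF1 replicate 2. T cell genes shifted higher, with 8 of 16 risen and 1 fallen (9 and 1 adjusted over the list alone, camera adjusted p = 0.000461, and adjusted p = 0.418 with an estimated correlation). Cd3g rose by 2.06 and Cd3d by 1.38, while Thy1 (-0.86) fell. Of T cell genes, 4 rose without control replicate 1, SF1 replicate 1 or SF1 replicate 2, and 5 without control replicate 2 or SF1 replicate 3. Natural killer cell genes (6 of 13 risen, 0 fallen, also adjusted over the list alone, camera adjusted p = 0.00452) and mast cell genes (6 of 11 risen, 0 fallen, 7 and 0 adjusted over the list alone; 8.46e-05) also shifted higher, both at adjusted p = 0.288 with an estimated correlation. Gzmb (1.38) and Gzmc (1.00) led the first and Cpa3 (1.34) and Cma1 (1.24) the second.

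Interferon response genes shifted higher, with 11 of 26 risen and 1 fallen (13 and 2 adjusted over the list alone, camera adjusted p = 1.36e-05, and adjusted p = 0.418 with an estimated correlation). Cxcl10 (1.82) and Cxcl9 (1.76), chemokines for T cells, rose most, and Rsad2 (-0.49) fell, a call lost without control replicate 1 or any SF1 replicate (highest adjusted p = 0.0911). The count of risen interferon genes was 4 without control replicate 1, 7 without control replicate 2 or 3, 3 without SF1 replicate 1, 5 without SF1 replicate 3 and 10 without SF1 replicate 2, and 2 fell without control replicate 3. Complement genes shifted higher, with 5 of 15 risen and 1 fallen (5 and 3 adjusted over the list alone, camera adjusted p = 0.0451, and adjusted p = 0.418 with an estimated correlation). Cfi rose by 1.35 and Cfp fell (-0.50). The complement call was lost without control replicate 3, SF1 replicate 1 or SF1 replicate 2 (highest 0.0877), and 3 members rose without SF1 replicate 1 or SF1 replicate 3.

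Of 14 neutrophil genes, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.00514, and adjusted p = 0.568 with an estimated correlation). These were Ltf and Lcn2 (3.57), which uterine epithelium also expresses. S100a8, which was not called, read 11518 in SF1 replicate 2 but 327 and 192 in SF1 replicates 1 and 3, and the list's call was lost without SF1 replicate 2 (0.0998). Fat cell genes shifted lower, with 0 of 14 risen and 4 fallen (0 and 5 adjusted over the list alone, camera adjusted p = 0.00516, and adjusted p = 0.554 with an estimated correlation). Fallen fat cell genes numbered 2 without control replicate 2 and 1 without control replicate 3, SF1 replicate 2 or SF1 replicate 3. Thrsp (-1.21) fell most, and the call of Retn (-0.64) was lost without any of 4 arrays (highest adjusted p = 0.137). Adipoq, not called, read 405 in SF1 replicate 3 and between 1505 and 3592 in the other arrays. Skeletal muscle genes shifted lower, with 0 of 17 risen and 3 fallen, also adjusted over the list alone (camera adjusted p = 0.0441, and adjusted p = 0.568 with an estimated correlation), a call lost without control replicate 3 (0.168) or SF1 replicate 1 (0.0723). Acta1 (-0.50) and Eno3 (-0.38) fell most, and lost their calls in 4 and 3 of the fits that left out 1 array (highest adjusted p = 0.0946 and 0.074). Fallen skeletal muscle genes numbered 0 without control replicate 2 or SF1 replicate 1, and 1 without control replicate 3, SF1 replicate 2 or SF1 replicate 3.

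The remaining lists did not shift by camera. Mucins and secreted epithelial proteins had 8 of 23 risen and 4 fallen, also adjusted over the list alone (camera adjusted p = 0.0894), with Ltf and Pigr (3.70), which carries antibodies across epithelia, higher and Ctse (-1.47) and Wfdc2 (-0.93) lower. That list was called without control replicate 2, SF1 replicate 1 or SF1 replicate 3 (lowest 0.0392). Uterine gland genes had 3 of 18 risen and 7 fallen (4 and 7 adjusted over the list alone, camera adjusted p = 0.582), with Clu (2.27) and Foxa2 (0.80) higher and Cxcl15 and Lgr5 (-1.40) lower. Ion and water transport had 7 of 27 risen and 4 fallen (8 and 5 adjusted over the list alone, camera adjusted p = 0.529). Car12 (2.34) was higher and Slc26a7 (-1.55) and the water channel gene Aqp1 (-0.82) were lower, while Slc26a4 (1.61) lost its call in 4 of the fits that left out 1 array (highest adjusted p = 0.101). Prostaglandin genes had 3 of 18 risen and 7 fallen, also adjusted over the list alone (camera adjusted p = 0.519), with Ptgis (0.77) and Ptgir (0.70) higher and Ptger4 (-1.07) and Pla2g4a (-0.98) lower. Cystic disease genes had 2 of 16 risen and 3 fallen (2 and 4 adjusted over the list alone, camera adjusted p = 0.905), with Umod (4.35) and Pkhd1 (1.22) higher and Cys1 (-0.78) lower, and only 1 member fell when control replicate 1 or 2 or any SF1 replicate was left out. Extracellular matrix had 2 of 35 risen and 5 fallen (2 and 7 adjusted over the list alone, camera adjusted p = 0.448), with Fn1 (-1.34) and Col18a1 (-1.28) lower. Timp1 (1.82) and Mmp23 (0.38) were called higher, and lost their calls in 4 and 3 of the fits that left out 1 array (highest adjusted p = 0.107 and 0.0695). Risen matrix genes numbered 0 without control replicate 2 or SF1 replicate 1, and 1 without control replicate 1, control replicate 3 or SF1 replicate 2.

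Few genes were called in the other marker lists, and the counts were the same adjusted over the list alone unless given. Of 32 cell cycle genes, Rrm2 (0.71) rose and 0 fell (camera adjusted p = 0.821). Of 17 ovary markers, Inha (0.78) rose and Foxl2 (-1.17) and Nlrp5 (-0.58) fell (camera adjusted p = 0.216). B and plasma cell genes had 2 of 15 risen (3 adjusted over the list alone, camera adjusted p = 0.0814), and were called without control replicate 3 (0.0282) or SF1 replicate 1 (0.0103), but 0 members rose without control replicate 1, SF1 replicate 2 or SF1 replicate 3. Immediate early genes had 3 of 24 risen and 1 fallen (camera adjusted p = 0.125), and were called without SF1 replicate 3 (0.0281), but 1 rose without control replicate 3, 0 rose without SF1 replicate 1, and 0 fell without any 1 array. Eosinophil genes had 2 of 8 risen and 1 fallen (0.497), nerve and glia 1 of 12 risen and 1 fallen (0.901), and mesothelium 0 of 11 risen and 1 fallen (0.484). Without SF1 replicate 1, 1 eosinophil gene rose and 0 fell, 0 nerve and glia genes rose and 0 mesothelium genes fell. Without control replicate 3, 1 eosinophil gene rose and 0 fell and 0 mesothelium genes fell. Without SF1 replicate 2, 1 eosinophil gene rose and 0 fell, 0 nerve and glia genes rose and 2 ovary markers rose. Without control replicate 1, 1 eosinophil gene rose and 0 mesothelium genes fell. Without SF1 replicate 3, 2 cell cycle genes rose, and 0 eosinophil or mesothelium genes fell. Without control replicate 2, 0 eosinophil genes fell. Lymphatic endothelium (7 measured, 0.519), erythrocytes (5 measured, 0.484) and squamous epithelium (20 measured, 0.878) had 0 called genes by limma, and 1 squamous gene rose without SF1 replicate 1. The median and mean differed in sign for uterine glands (0.06 and -0.17), mucins (-0.03 and 0.70), ion transport (-0.04 and 0.11), cystic disease (-0.09 and 0.23), cell cycle (-0.02 and 0.01), nerve and glia (-0.02 and 0.02) and squamous epithelium (-0.06 and 0.00), and the test had the sign of the mean except for squamous epithelium.

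**Figure D2:**
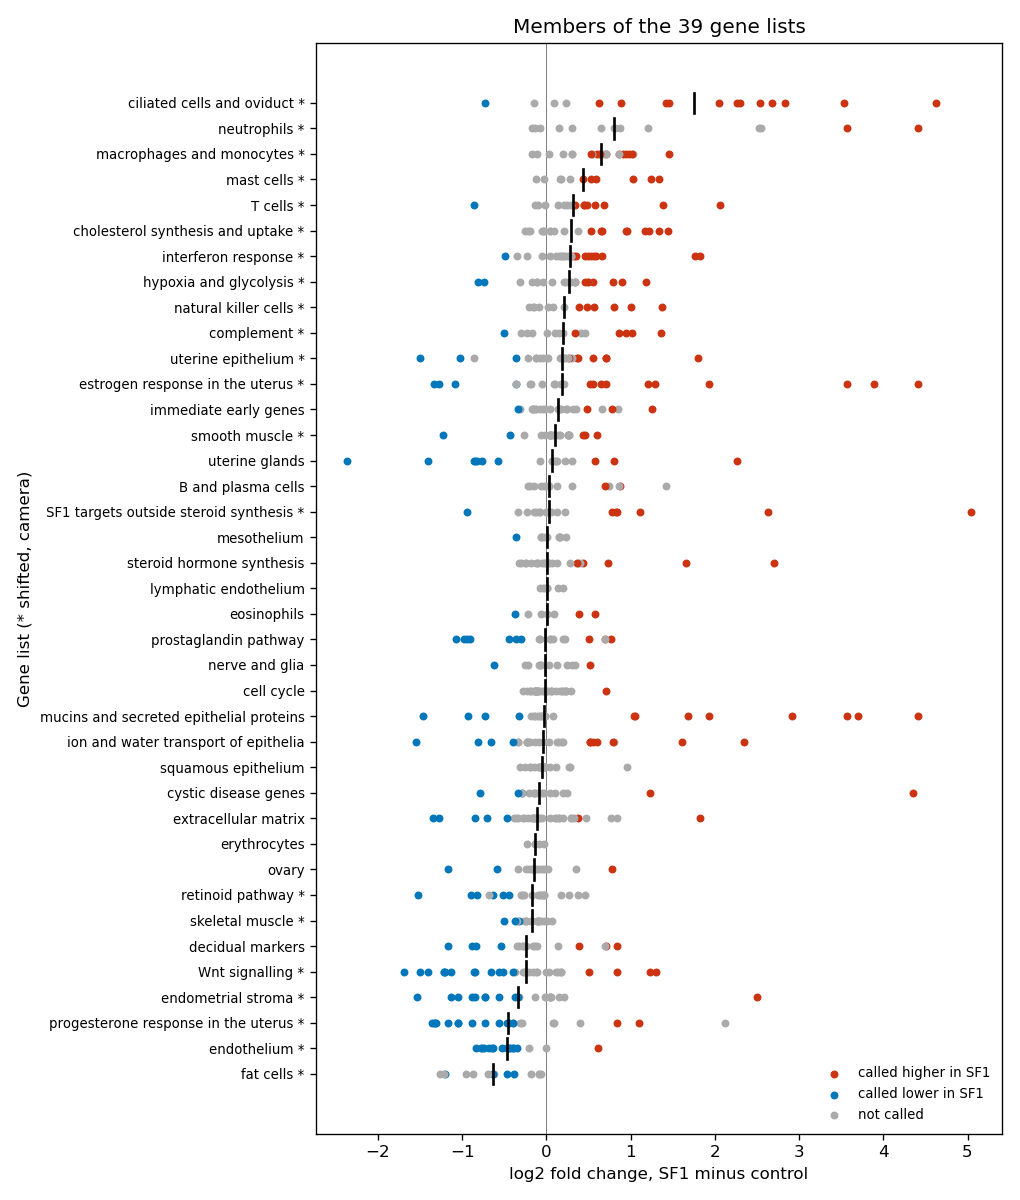
Log2 fold change (SF1 minus control) of each measured member of the 39 gene lists, 1 point per gene, coloured by whether limma called it, with a black tick at each list's median and an asterisk where camera called the list. The median of the ciliated list, 1.75, is the highest, and that of fat cells, -0.63, the lowest.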

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

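The tests of adrenal and ovarian tissue, of oviduct and epithelium, of the Pgr allele and of other splits of the arrays were chosen or written after the values they use had been seen at least in part, and the test of intestinal tissue was written before. Of 19 control probe sets for mouse transcripts, which entered no comparison, 3 were higher in all SF1 arrays than in any control array. All 3 were for Gapdh, with log2 differences of 0.36, 0.44 and 0.37 for the 3', 5' and middle parts. Chance gives this order for 5% of probe sets, and the parts of 1 transcript are not independent. The opposite order was not counted. Some mouse control probe sets fell by a like or larger amount. Among them were a pyruvate carboxylase probe set (log2 difference -0.57) and the murine b1 probe set (-0.41).

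Genes of motile cilia were higher in SF1. Oviduct tissue carried along would bring Ovgp1, which fell instead (log2 change -0.7331, adjusted p = 0.00888). Ovgp1 already read 279 ± 48.1 (SD) in control, so its level in the uterus itself may have fallen. This 1 gene cannot exclude oviduct tissue. A larger share of epithelium would raise epithelial genes alike, but the 75th percentile of the epithelium list was 0.2943, against a median of 1.75 for the ciliated list. A change within the epithelium of SF1 uteri stays open, as a hypothesis.

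Star, Cyp11a1 and Nr0b1 were higher in SF1 together with the granule genes Chga and Chgb. Of these, Cyp11a1 was the least certain, since 2 of its 3 probe sets were not called. Its call was also lost in 3 of the fits that left out 1 array. Adrenal tissue would bring Cyp21a1, Th, Dbh and Pnmt, whose median log2 change was -0.1159. In control, Dbh (383), Pnmt (333) and Cyp21a1 (166) read well above Chga (22.9) and Nr0b1 (23.65). Carried tissue could raise Chga or Nr0b1 while moving Dbh, Pnmt and Cyp21a1 little. Th, which read 54.9 in control, did not rise either, but a small share of adrenal tissue is not excluded. Ovarian tissue would bring Hsd3b1, Akr1c18, Cyp17a1, Foxl2 and Amh, of which the highest log2 change was 0.03037 (Akr1c18). Inha, another ovary marker, went the other way and rose (0.78, adjusted p = 0.000505). It had the highest change of the 17 measured ovary markers, below that of Star (2.70). The rise from carried tissue depends on a gene's level in control and in that tissue, and the latter was not measured. Cyp17a1 (97.6) and Akr1c18 (146) read near Star (114) in control, so a rise like that of Star would have shown in them, and they were not called. Foxl2 read 1807 in control, where carried tissue would show less. Because the levels of these genes in ovarian tissue were not measured, such tissue is not excluded. The rise of Inha, also a member of the list of SF1 targets, is left open. Intestinal tissue would raise its abundant epithelial genes, whose median was -0.08458 over 10 genes, although Krt20 (0.90) and Vil1 (0.41) were called higher. In control these genes read from 51.4 (Vil1) to 526 (Lgals4), above Chga (22.9) and Pyy (37.8). A small share of intestinal tissue could move them less than Chga or Pyy, and is not excluded. Expression within SF1 uteri may remain as a hypothesis.

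Pgr was lower in SF1. Loss of 1 Pgr allele to the Cre knock-in may lower Pgr by 1 on the log2 scale. The brightest probe set gave -1.337, with a 95% interval from -1.53 to -1.14, while the intervals of the other 2 probe sets held -1. Cre was carried by the SF1 group alone, so allele dose and SF1 cannot be told apart.

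The 6 arrays can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 2998 genes and the highest other split 0, and 1 of the 10 splits gave as many genes. Every other split put both control and SF1 arrays into each group, so a real difference would widen the spread within groups. A low count of genes in those splits would then be built in. For lists the real split gave 21 and the highest other 11, and 1 of the 10 gave as many. The other splits kept part of the difference between SF1 and control, so lists called there need not be false calls.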

How the results depend on the processing

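The alternatives were fixed in advance, but the fits that left out 1 array were changed after the data were seen. They first chose a gene's probe set again, and now keep the probe set of all 6 arrays, as do the other alternatives that use 1 probe set per gene. Genes changed, SF1 against control, numbered 2998 and ranged from 1933 to 2365 with 1 array left out, and from 1920 to 2371 with the probe set chosen again. Genes higher in SF1 ranged from 1025 to 1294, and from 1013 to 1303 with the probe set chosen again. Genes lower in SF1 ranged from 908 to 1118, and from 907 to 1113 with the probe set chosen again (962 without control replicate 1). These fits had fewer arrays. A fold of at least 1.5 in addition left 1279 genes changed, SF1 against control, with 780 for genes higher in SF1 and 499 for genes lower in SF1, and an adjusted p under 0.01 left 1558, 848 and 710, as stricter thresholds must. The replicate block gave 2071 genes changed, SF1 against control, and 932 for genes lower in SF1. Replicate numbers did not pair the arrays: the deviations of arrays with the same number correlated at -0.0633, -0.101 and -0.184, and 0 arrays correlated best with their own number. Gene lists shifted numbered 18 to 23 with 1 array left out, and 0 (0 higher, 0 lower) by camera with an estimated correlation, where 4 had an unadjusted p under 0.05. Mixed fry called 33, but it asks whether members change in either direction, not whether a list shifts.

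Pgr, SF1 against control, fell under every alternative, from -1.39 to -1.27 with 1 array left out, and Nr5a1, SF1 against control, which was not called, ranged from -0.054 to 0.085. Values that were not called also turned sign. Bpgm log2 fold change was 0.0051 after quantile normalization, 0.021 after median centring and 0.23 as the mean of its probe sets. Cyp17a1 log2 fold change was 0.049 after quantile normalization and 0.045 after median centring, and ranged from -0.16 to 0.076 with 1 array left out, and Mmrn1 log2 fold change from -0.052 to 0.040. Cyp11a1 log2 fold change was called, and turned to -0.22 without SF1 replicate 1 and -0.33 without SF1 replicate 2 when the probe set was chosen again, since another of its probe sets was then the brightest. Array medians were lower in SF1 (-0.0517 on the log2 scale), so median centring raised the log2 changes of all genes alike, by more than the falls of Bpgm and Cyp17a1. With 1 array left out, named genes other than Nr5a1 and Pgr lost their call in 80 of 720 comparisons and turned sign in 5, and lists lost it in 12 of 234 and gained it in 7. Under the other alternatives, these genes lost it in 41 of 1063 and turned sign in 5, and lists lost it in 48 of 467 and gained it in 6.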

Other observations

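The tests in this part use gene groups formed after the highest genes had been seen. The test of the neuroendocrine genes was written before any of their values had been seen, and that of the cilium families after some had been.

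Some genes of hormone-secreting cells rose in SF1 uteri. Chga rose from 22.9 ± 2.15 to 920 ± 406 intensity units, Chgb from 28.9 ± 6.37 to 752 ± 314, and Scg2 (log2 change 2.87) and Ddc (2.78), the aromatic amino acid decarboxylase gene, rose with Pyy. These were chosen after their values were seen. A hypothesis is that a wider neuroendocrine program may have been raised. Of 9 further genes named before their values were seen, 6 rose and 0 fell, among them the transcription factor genes Neurod1 (1.18) and Insm1 (0.85) and the peptide-processing gene Cpe (0.46), and as a list they shifted higher (camera p = 0.0005568; p = 0.0777 with an estimated correlation). Scg3, Syp and Vgf were not called. Chga, Chgb, Scg2, Pyy, Ddc, Neurod1 and Insm1 each read highest in SF1 replicate 1 and lowest in SF1 replicate 3.

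The rise of cilium genes may reach beyond the fixed list. Of 40 other genes of the Cfap, Dnah, Rsph, Tekt and Drc families, 20 rose and 2 fell, with a median log2 change of 0.32 (camera p = 4.814e-13, and p = 0.042 with an estimated correlation). Cfap65 was 15.1-fold and Cfap52 was 9.95-fold higher, while Rsph3a fell to 0.545 of control. Cfap65 and Cfap52 each read highest in SF1 replicate 3 and lowest in SF1 replicate 2, an order that Cfap69 and Cfap36, also higher, did not share.

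The 4 cre spike-in control probe sets, which detect a hybridization control added to every sample, differed by a median log2 value of 0.03 and read at least 8141 in control arrays, so they do not measure the Cre allele.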
